A study of Mus musculus with 5 samples.

How the data were processed

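Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mouse bone marrow macrophages of the C57Bl/6 background. The source and cell type labels call them polarized in culture to M2, the alternative state, while every sample title carries M0, which the labels do not explain, so the state of the cells rests on the first labels alone. Formaldehyde-fixed chromatin was sonicated and precipitated with an antibody to c-Maf, a basic leucine zipper transcription factor, or with normal rabbit immunoglobulin as isotype control, per the labels' protocols. The series has 5 samples. They are 2 c-Maf antibody libraries, 2 isotype libraries and 1 input library. The libraries of each antibody carry the numbers 3 and 4 and the input carries the number 4. The series' design text calls the 2 numbers biological replicates. The input was used here only as it enters the authors' peak calls.

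Each of the 4 antibody libraries has its own peak list, so peaks were called per library and not on pooled samples, per the file headers. The headers name MACS 2.1.1.20160309, single-end reads, a p-value cut-off of 0.01, 1 tag kept per position, scaling of the larger library towards the smaller, and the number 4 input as control for all 4 lists. The effective genome size in the headers is the human setting. The submitters' processing notes name the mm10 build, FastQC, MACS 1.4.2 and MACS2. The aligner is not given in the sources used here. Each deposited peak has a start, end and summit position, a pileup signal at the summit computed by the authors, a fold enrichment, which is the ratio of that pileup to the local input level, and the −log10 of its p-value and of its q-value, per the file headers. The ratio has 1 added to both its parts: p-values recomputed on that basis matched the deposited ones within 0.02 on the −log10 scale for at least 99.99% of the peaks of each list, so fold enrichments are smaller than a plain ratio would be. These scores are the authors' own and were used only to describe, rank or filter peaks within one list.

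Depth was nearly equal. After duplicate filtering the c-Maf antibody libraries held 22017759 (number 3) and 21655683 (number 4) tags, the isotype libraries 21833446 and 21779401, and the input 21370300. The highest of the 4 antibody libraries was 1.017 times the lowest. A typical peak held few tags, with a median summit pileup of 3.92 to 5.92 scaled tags per list, so a single weak peak carries a large counting error. The fragment length that MACS estimated was 63 bp and 60 bp for the c-Maf antibody libraries of numbers 3 and 4, and 53 bp and 56 bp for the isotype libraries, close to the tag size of 50 bp.

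Peaks of all 4 lists that overlapped by at least 1 bp were merged into regions, and each region was described by the lists that held it. A c-Maf-only region held a peak of both c-Maf antibody libraries and of neither isotype library. An isotype-only region was defined with the antibodies exchanged and gives the background of the same definition. Overlap between lists was compared with 1000 random circular shifts of one list along each chromosome, taking the largest peak end as the chromosome length. The one-sided permutation p counts shifts with as much overlap, and its smallest possible value is 0.001. For region counts, both lists of one antibody were shifted and the other 2 kept in place. With 2 libraries against 2 there are 3 splits, so no test over libraries can give a share under 0.333, and every p-value here compares the regions of these libraries.

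Genes came from a RefSeq gene table of the GRCm38.p6 assembly, which has the coordinates of mm10, with 21883 protein-coding genes on assembled chromosomes. The table gives gene spans without strand or exons. The planned distance from a transcription start was therefore replaced by the distance from either gene boundary, and the planned exon and intron classes by inside or outside a gene. Shares of regions have 95% Wilson intervals and were compared with two-sided Fisher's exact tests. The 13 gene lists fixed before the data were examined hold 212 distinct matched genes, and 1 entry had no match. Genes with a region within 5 kb of a boundary were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 13 lists. Motif content was not analysed here, because no genome sequence was used.

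The rule for named genes was fixed before the data were examined. It takes Maf, Csf1r, Il10, Arg1 and Mrc1 in every library, up to 30 listed genes with a c-Maf-only region within 5 kb, the 10 c-Maf-only regions on assembled chromosomes with the best mean within-list percentile rank of p, and the 5 best isotype-only regions and 5 best regions held by all lists. Genes named outside it are said to be so where they appear. Some items that the rule takes are not reported here.

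Other settings, fixed before the data were examined, were a p-value of 1e-10 or smaller, a fold enrichment of 10 or more, equal list lengths (the 15568 strongest peaks of each list), a 50% reciprocal overlap, summits within 200 bp, autosomes and X only, peaks moved by 10 to 100 kb in place of circular shifts, matching of libraries by number, and each library left out. Settings chosen after seeing the data were p-values of 1e-05 or smaller, q-values of 0.05 or smaller, lists of equal length from the strongest 100 to 5000 peaks, removal of repeat-like sequence (unplaced sequence, chromosome Y and 10 kb around regions held by all lists), gene bodies added to the 5 kb window, and neighbouring list genes counted once. Alternatives with shifts used 200 shifts. The steps were tested on simulated data made from 116154 peaks, in which 198 of 200 planted c-Maf-only regions and 100 of 100 planted isotype-only regions were recovered, among 223 and 150 regions called. The planted peaks of a region overlapped by construction, so this checks the counting steps and not the sensitivity on these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.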

Results

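Peaks from 2 c-Maf antibody libraries and 2 isotype libraries of bone marrow macrophages were compared to find genomic regions that the c-Maf antibody recovered in both replicates and the isotype control did not. The cell type label calls the cells M2-polarized, but the sample titles carry M0, and the labels do not resolve the difference. The c-Maf antibody lists held 23434 (number 3) and 17620 (number 4) peaks. The isotype lists held 58732 and 15568 peaks. Few peaks passed a q-value of 0.05, with 717 and 505 in the c-Maf antibody lists and 244 and 408 in the isotype lists. The longest list, isotype number 3, thus had the fewest peaks at that level. Merging gave 111856 regions, and 97.5% of them were held by 1 list alone.

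The strongest regions shared by the c-Maf antibody libraries lay inside or outside genes of varied function. The region with the best mean rank was on chromosome 1 at 12616179 to 12616361 (mm10 throughout), 75.8 kb outside Sulf1, which encodes a heparan sulfate sulfatase. Its fold enrichment was 15.06 in the c-Maf antibody library of number 3 and 10.37 in that of number 4. The next lay inside Rhoh, a GTPase gene of blood cells, on chromosome 5 at 65883428 to 65883624, with fold enrichments of 15.49 and 10.54. A region on chromosome 2 at 126591444 to 126591666 was 2.0 kb outside Hdc, which encodes histidine decarboxylase, the enzyme that makes histamine, with fold enrichments of 13.20 and 11.30. These 3 regions were the ones that kept both c-Maf antibody peaks at a fold enrichment of 10 or more.

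The other 7 of the 10 best regions had fold enrichments between 6.81 and 14.97 in number 3 and between 7.08 and 9.19 in number 4. Regions inside genes were found in Fbxo34 (chromosome 14, 47483147 to 47483352), Esrrb, an orphan nuclear receptor gene (chromosome 12, 86488084 to 86488402), Slc9a9, a sodium-proton exchanger gene (chromosome 9, 94696764 to 94697003), and Spock1 (chromosome 13, 57568514 to 57568696). Regions outside genes lay 93.0 kb from Marcks, a protein kinase C substrate gene (chromosome 10, 37231932 to 37232123), 122.7 kb from Smim20 (chromosome 5, 53401209 to 53401367) and 6.0 kb from Nme4, a mitochondrial nucleoside diphosphate kinase gene (chromosome 17, 26101565 to 26101850). The nearest gene is named by position only.

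In all, 491 regions were c-Maf-only and 409 were isotype-only. Circular shifts of the c-Maf antibody lists gave a mean of 41.63 c-Maf-only regions and at most 63, an 11.8-fold excess (permutation p = 0.001, one-sided, the smallest possible). Shifts of the isotype lists gave a mean of 60.77 isotype-only regions and at most 88, a 6.73-fold excess (permutation p = 0.001, one-sided). The order turned when shared meant summits within 200 bp, with 577 c-Maf-only and 621 isotype-only regions. As deposited, the c-Maf antibody pair was not the pair with the most exclusive regions, since the c-Maf antibody and isotype libraries of number 3 shared 580. With each list cut to its 15568 strongest peaks, c-Maf-only regions numbered 391, isotype-only regions 160 and the highest mixed pair 267. Among peaks with a q-value of 0.05 or smaller the counts were 47, 10 and 16. Summed over both sides, the 3 splits of the libraries gave 900 exclusive regions for antibody, 822 for number and 691 for the crossed split as deposited, and 551, 390 and 329 at equal list lengths. With 3 splits no share under 0.333 is possible.

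**Figure D1:**
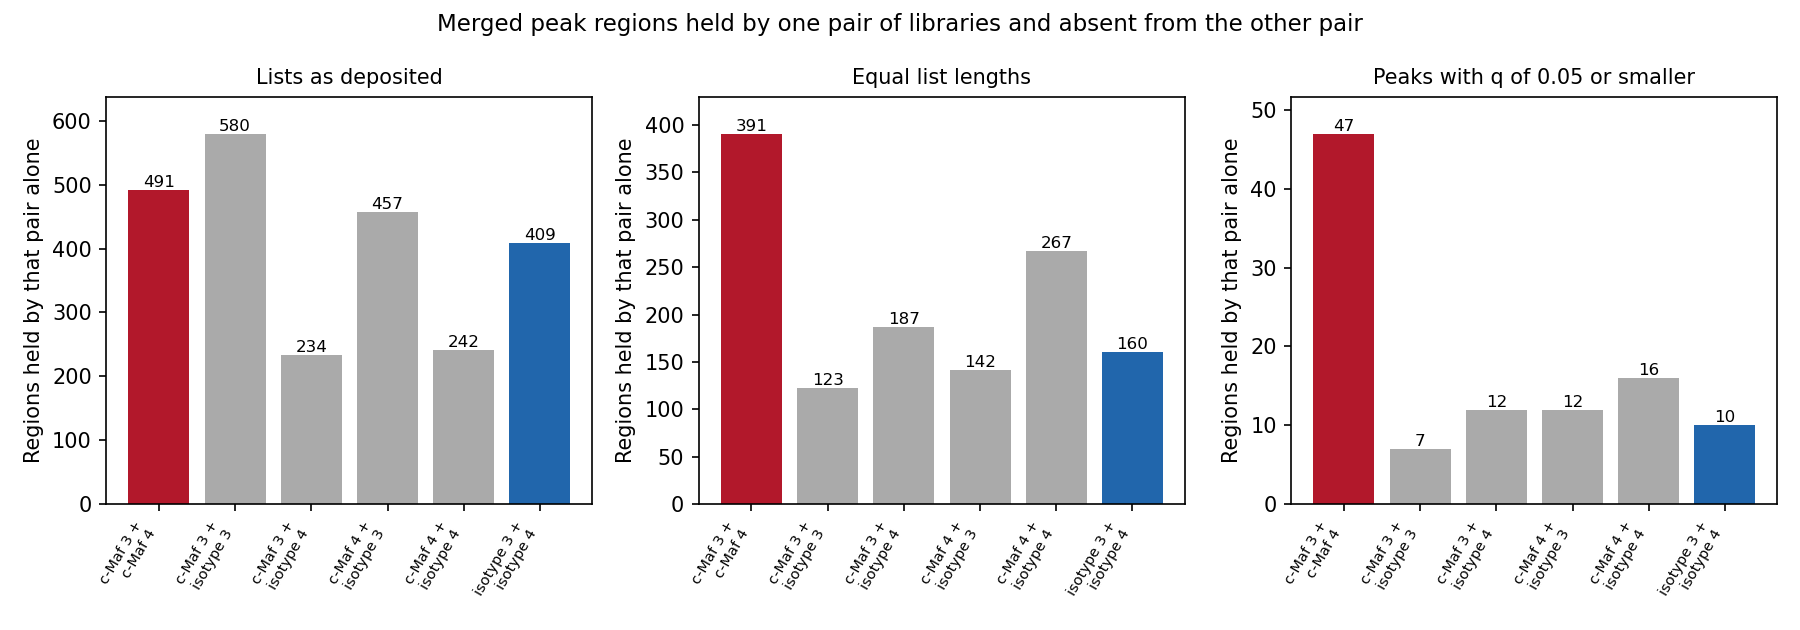
Bars give the number of merged regions held by each pair of libraries and by neither of the other libraries, for lists as deposited, lists of equal length and peaks with a q-value of 0.05 or smaller. The c-Maf antibody pair (red) had 491, 391 and 47 regions, and the isotype pair (blue) 409, 160 and 10.

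**Figure D2:**
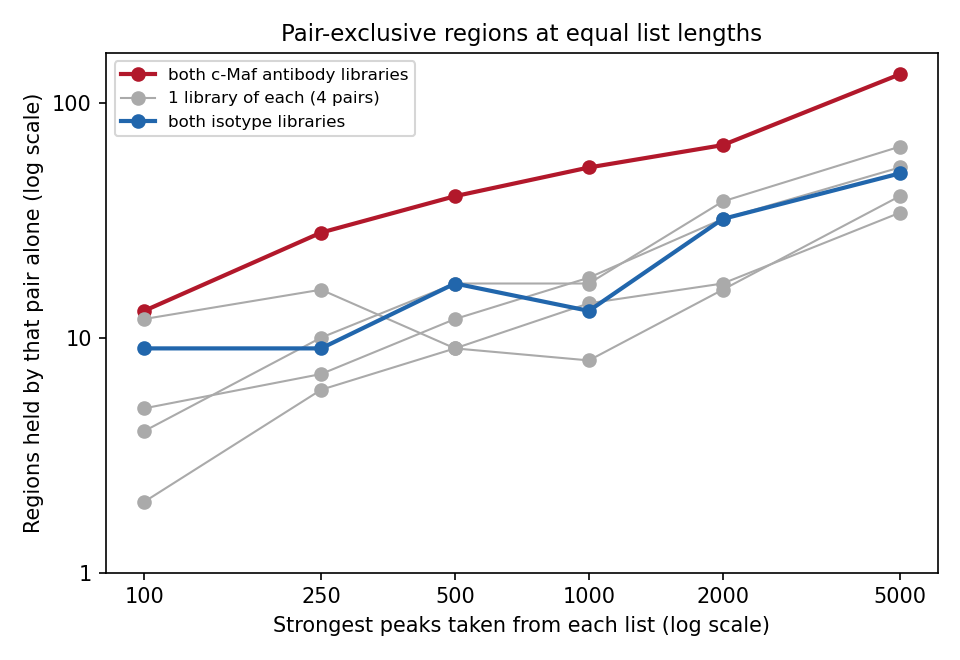
Lines give the number of pair-exclusive regions (vertical, log scale) against the number of strongest peaks taken from each list (horizontal, log scale). The c-Maf antibody pair had 13 regions at 100 peaks and 132 at 5000, and the isotype pair 9 and 50. At 100 peaks a mixed pair had 12.

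Genes that mark macrophages and genes reported as c-Maf targets had c-Maf-only regions near their boundaries more often than other genes did. Of 21 macrophage identity genes, 4 had a c-Maf-only region within 5 kb of a boundary, namely Csf1r, Itgam, Aif1 and Mertk (Fisher's exact test, adjusted p = 3.32e-05). Of 20 reported c-Maf targets, 4 had one, namely Csf1r, C1qa, C1qb and C1qc (Fisher's exact test, adjusted p = 3.32e-05). Among all 21883 protein-coding genes the share was 0.558%, or 122 genes. Csf1r stands in both lists, and the 3 C1q genes have 2 regions between them. Within 1 kb of a boundary, the macrophage identity list had 1 gene, Itgam, and did not pass (Fisher's exact test, adjusted p = 0.135). With neighbouring genes of a list counted once, the target list had 2 of 18 loci (Fisher's exact test, adjusted p = 0.028). Isotype-only regions lay near 43 genes, 0.196% of all, none of them in any of the 13 lists, and at that share few or none of the listed genes would be expected. Set directly against those 43 genes, the 122 genes near c-Maf-only regions gave 4 against 0 for each list (Fisher's exact test, p = 0.574), the most extreme split of 4 genes in that direction, so this comparison could not have passed. With either c-Maf antibody library left out, the same genes still had a region, but no list passed the threshold. A lone list is then not filtered by a replicate, so those genes could hardly lose their regions. The share of all genes with a region also rose. It was 9.62% without number 3 and 14.5% without number 4. The c-Maf-only regions near listed genes were weak: of the 9 listed genes with one, only Idh1 had a q-value of 0.05 or smaller in both c-Maf antibody libraries.

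At Csf1r, which encodes the receptor for the macrophage growth factor CSF1, 2 c-Maf-only regions lay inside the gene, and 1 of them was within 5 kb of a boundary, on chromosome 18 at 61108616 to 61108932, 3044 bp from it. Its fold enrichment was 7.20 in number 3, with a −log10 q of 4.38, and 4.76 in number 4, with a −log10 q of 0.41. The second library's peak therefore did not pass a q-value of 0.05. The other region joined peaks at 61120655 to 61120744 and 61120660 to 61120719, with fold enrichments of 4.35 and 3.21. The C1q genes, which encode the chains of complement component C1q, lie side by side on chromosome 4. One region at 136886162 to 136886374 overlapped a boundary of C1qb, with fold enrichments of 5.38 and 4.94, and another at 136892952 to 136893110 lay between C1qc and C1qa, with fold enrichments of 5.46 and 4.45. No isotype peak was found in either locus or within 10 kb of it.

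**Figure D3:**
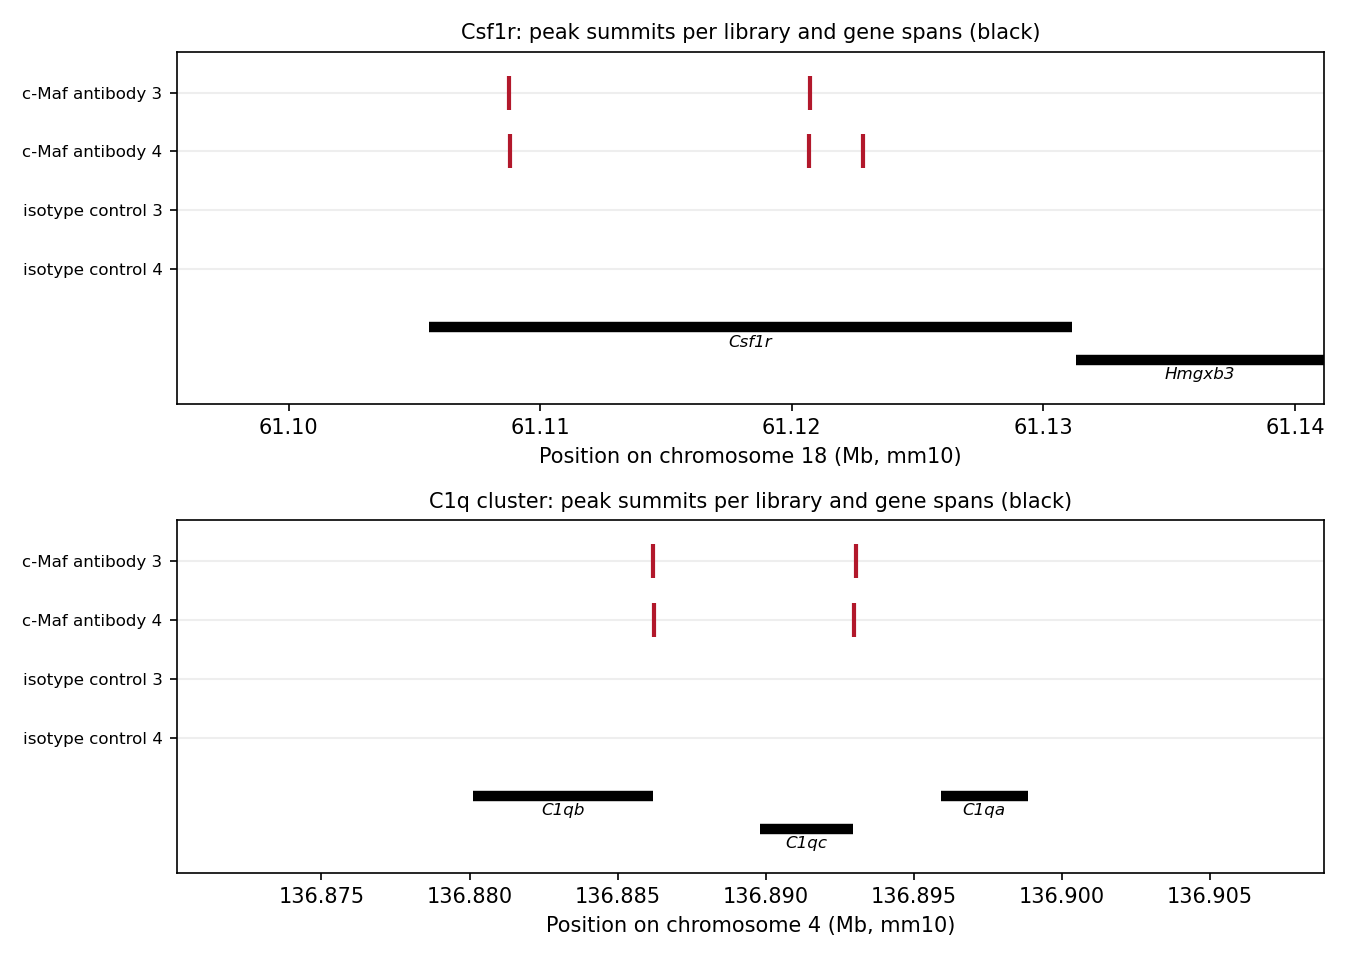
Vertical marks give the summit of each peak in the 4 libraries (rows) around Csf1r on chromosome 18 and the C1q genes on chromosome 4, with gene spans in black and position in Mb. Marks have no scale of height, and both isotype rows are empty over these windows.

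Itgam, which encodes the integrin chain CD11b, held a region on chromosome 7 at 128063612 to 128063742, with fold enrichments of 4.55 and 6.03. Aif1, which encodes the calcium-binding protein IBA1, held one on chromosome 17 at 35172640 to 35172805, with fold enrichments of 5.84 and 4.68. The region near Mertk, a receptor for the uptake of dying cells, lay 3533 bp outside the gene, and its peak in number 4 was weak, with a fold enrichment of 2.96. Of the 20 genes in the citric acid cycle list only Idh1 had a region (Fisher's exact test, adjusted p = 0.344). Idh1 encodes the cytosolic NADP-dependent isocitrate dehydrogenase, which acts outside the mitochondrial cycle. The region overlapped a gene boundary on chromosome 1 at 65186449 to 65186582, with fold enrichments of 6.32 and 6.68. Of 12 neutrophil and mast cell markers only Fcer1a had one (Fisher's exact test, adjusted p = 0.281). No c-Maf-only region lay within 5 kb of a boundary of the 24 genes of alternative activation, or of the listed genes of classical activation, glycolysis, the pentose phosphate and hexosamine pathways, T and B cells, fibroblasts, lens crystallins, neurons or housekeeping, which all had an adjusted p of 1.0 by Fisher's exact test.

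Of the 5 genes given here for every library, Csf1r was the only one with a c-Maf antibody peak in the gene or within 5 kb, with 2 peaks in number 3 and 3 in number 4. Maf, which encodes c-Maf, had its nearest c-Maf antibody peaks 38.1 kb and 52.8 kb away. At Il10, an anti-inflammatory cytokine gene, the nearest c-Maf antibody peaks lay 28.3 kb and 66.3 kb away, and the isotype library of number 3 had a peak in the gene. At Arg1, the arginase gene of alternatively activated macrophages, they lay 30.6 kb and 108.1 kb away. At Mrc1, which encodes the mannose receptor, they lay 216.6 kb and 189.0 kb away, and the isotype library of number 3 again had a peak in the gene.

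c-Maf-only regions lay inside genes more often than isotype-only regions, in 204 of 491 (41.55%, Wilson interval 37.27% to 45.96%) against 114 of 409 (27.87%, 23.75% to 32.41%, Fisher's exact test, p = 1.92e-05). They also lay within 1 kb of a gene boundary more often, in 6.31% (4.48% to 8.82%) against 3.18% (1.87% to 5.36%, Fisher's exact test, p = 0.0305). The second difference did not pass the test at equal list lengths, with 6.91% against 6.25% (Fisher's exact test, p = 0.853). It turned direction without the c-Maf antibody library of number 3, with 2.89% against 3.26%, or of number 4, with 3.46% against 3.73%. It kept its direction without the isotype library of number 3, with 6.4% against 2.74%, or of number 4, with 6.49% against 2.46%. The first passed at equal list lengths, with 42.97% against 24.38% (Fisher's exact test, p = 4.33e-05), and without the c-Maf antibody library of number 3 (Fisher's exact test, p = 4.68e-06) or 4 (Fisher's exact test, p = 2.38e-07). It did not pass without the isotype library of number 3, with 41.05% against 37.86% (Fisher's exact test, p = 0.145), or without that of number 4, with 39.65% against 39.35% (Fisher's exact test, p = 0.897). Nor did it at q-values of 0.05 or smaller, with 48.94% against 20% (Fisher's exact test, p = 0.16), or at p-values of 1e-10 or smaller, with 44.44% against 0.0% (Fisher's exact test, p = 0.491). Lists of a lone library, not filtered by a replicate, gave similar shares inside genes for both antibodies. They were 38.89% (number 4) and 41.15% (number 3) for the c-Maf antibody, and 37.86% (number 4) and 39.35% (number 3) for the isotype. All lay within the Wilson interval of the c-Maf-only share and above that of the isotype-only share. The difference inside genes thus reflects a low isotype-only share and shows no preference of c-Maf-only regions for gene bodies. At gene boundaries, by contrast, every lone list lay below the Wilson interval of the c-Maf-only share. Within 1 kb, lone lists had 3.46% (number 3) and 2.89% (number 4) for the c-Maf antibody, and 2.46% and 2.74% for the isotype. Within 5 kb, they had 13.36% and 11.72% for the c-Maf antibody, and 10.78% and 11.34% for the isotype. Why was not tested.

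Regions held by all 4 lists numbered 174. Of these, 55 lay on the unplaced sequence JH584304, 36 on chromosome 11 and 22 on chromosome 5. The 5 best on assembled chromosomes lay inside Gm525 (chromosome 11, 89081833 to 89082040) and Smo (chromosome 6, 29748107 to 29748172), 34.7 kb from Zfp825, 4.5 kb from Sfi1 and 22.5 kb from Ly6c2, with mean fold enrichments of 2.82, 2.86, 2.59, 4.05 and 2.32. Of the 5 best isotype-only regions, 4 lay 538.1 kb from Trib2, 6.0 kb from Gm10354, 4.9 kb from Arl14ep and inside Sfi1, with mean fold enrichments of 7.85, 5.01, 6.70 and 3.50.

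All 6 pairs of lists overlapped more than circular shifts allowed. The c-Maf antibody pair shared 788 peaks of number 3, 11.3 times the mean of the shifts. The other pairs lay between 7.35 times, for the c-Maf antibody and isotype libraries of number 3, and 9.76 times, for those of number 4. The isotype pair was at 8.42 times. The order turned on autosomes and X alone, with 29.2 times for the c-Maf antibody pair and 32.2 times for the c-Maf antibody and isotype libraries of number 4. Every pair as deposited had a permutation p of 0.001 (one-sided, the smallest possible; adjusted p = 0.001).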

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

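Settings at q-values or at p of 1e-5, those without repeat-like sequence, the gene-place shares at equal list lengths, the gene-body window and neighbouring genes counted once were chosen after the data were seen. The 6 pairwise overlaps stayed above chance under each alternative that gave a ratio, but their sizes and order moved, as on autosomes and X alone (10.1 to 32.2 times). None exists at a fold enrichment of 10 or more, where the shifts gave no overlap: the c-Maf antibody pair shared 3 peaks (permutation p = 0.005) and the other 5 pairs 0 (permutation p = 1.0). c-Maf-only against isotype-only regions numbered 9 and 3 at p of 1e-10, 3 and 0 at a fold of 10, 82 and 44 at p of 1e-05, 47 and 10 at q of 0.05, 28 and 9 in equal lists as long as the shortest at q of 0.05, and 313 and 247 at 50% reciprocal overlap. Isotype-only regions numbered 160 at equal list lengths, 139 with repeat-like sequence also removed, and 621 with summits within 200 bp, against 577 c-Maf-only regions. Stricter settings keep fewer peaks by construction, but dropping isotype peaks can also add c-Maf-only regions. Of the 47 at q of 0.05, only 36 had no isotype peak at any level. With 1 library left out, c-Maf-only regions ranged from 531 to 22265 and isotype-only regions from 460 to 57336, because a lone list is then not filtered by a replicate. The share of c-Maf-only regions within 1 kb of a gene boundary was 0.0% at p of 1e-10 (both antibodies), 6.91% at equal list lengths (isotype-only 6.25%) and 12.77% at q of 0.05 (6 of 47 against 0 of 10), each no longer past the threshold, in the last case with fewer regions and a wider difference, and ranged from 2.89% to 6.49% with 1 library left out, where the direction turned without either c-Maf antibody library. There the c-Maf side is a lone list of 16543 or 22265 regions, not filtered by a replicate. Its shares of 2.89% and 3.46% lay near the 2.74% and 2.46% of lone isotype lists. The turn therefore says little about regions held by both c-Maf antibody libraries. Why the other settings lost the call was not tested. Gene lists past the threshold fell from 2 to 1 within 1 kb of a boundary, where macrophage identity was lost, and to 0 at p of 1e-10, and ranged from 0 to 2 with 1 library left out. Of the 10 named regions, 8 were found again at p of 1e-10 and 9 at 50% reciprocal overlap.

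No label says that libraries of one number share an animal or a day, and 2 such pairs are too few to show a pairing from the data. Exclusive regions of the same-number pairs numbered 580 and 242 as deposited, against 234 and 457 for the crossed pairs, and 123 and 267 against 187 and 142 at equal list lengths. With the number as a replicate block, c-Maf-only regions numbered 495 and isotype-only regions 411, 6.26% of c-Maf-only regions lay within 1 kb of a boundary and 2 gene lists passed, so no call changed. The planned motif alternatives were not run, because motif content was not analysed here.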

Other observations

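The genes in the first paragraph and the tests on isotype list length and on the isotype library of number 3 were chosen after the values were seen.

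Of the 47 c-Maf-only regions at a q-value of 0.05 or smaller, 36 had no isotype peak at any level, and 34 of these lay outside repeat-like sequence. Among those 34, 19 lay inside a gene, 7 within 10 kb of one and 8 farther away. The same steps left 4 of 10 isotype-only regions, with 0 inside a gene, against 2 of the 10 before these steps. So few isotype-only regions allow no comparison of shares. Beyond the 10 best, regions inside genes were found in Bcl2l11, which encodes the pro-apoptotic protein BIM (chromosome 2, 128128010 to 128128208, fold enrichments 5.59 and 9.81), Itgb5, an integrin chain gene (chromosome 16, 33922391 to 33922617, 7.67 and 6.11), E2f7, a cell cycle repressor gene (chromosome 10, 110781934 to 110782084, 5.84 and 5.91), and Acox3, a peroxisomal acyl-CoA oxidase gene (chromosome 5, 35591657 to 35591872, 8.26 and 5.95). Regions 8 bp from Zfp143, a transcription factor gene (chromosome 7, 110061518 to 110061681), and 10 bp from Eif4ebp1, a repressor of translation initiation (chromosome 8, 27260169 to 27260317), had fold enrichments of 8.10 and 7.08, and of 6.81 and 6.89. A region 6.9 kb from Fpr2, a formyl peptide receptor gene, had 5.53 and 5.71.

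At equal list lengths c-Maf-only regions outnumbered isotype-only regions 2.44 times. After removal of unplaced sequence, chromosome Y and 10 kb around regions held by all lists, the ratio was 2.60 (exact interval 2.13 to 3.18). That removal left 361 c-Maf-only and 139 isotype-only regions, against 391 and 160 before it, so it could hardly move the ratio. No repeat annotation was used, and repeats called in fewer lists stay open as a cause. Wider peaks in the c-Maf antibody libraries as the whole cause are argued against by a ratio of 2.01 (1.71 to 2.37) when summits within 200 bp were compared. The isotype library of number 3 had few exclusive regions with any list at equal list lengths (123, 142 and 160), but c-Maf-only regions were still 1.46 times (1.25 to 1.72) those of the highest pair without it. Binding of the antibody's target stays open as a hypothesis, as do other proteins the antibody may recognise, since neither motifs nor cells lacking c-Maf were analysed here. These intervals cover counting error only, and 2 libraries per antibody leave library differences open.

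The isotype list of number 3 was 3.77 times as long as that of number 4. More strongly enriched sites are argued against, because number 4 had 1.67 times (1.42 to 1.97) as many peaks at a q-value of 0.05 and 1.35 times (1.15 to 1.59) as many at a common p of 1e-07, but at p of 1e-05 number 3 had more, so additional weak sites stay open. A candidate explanation is the shorter fragment length of 53 bp, at which 3 tags pass the authors' p-value cut-off (p at 3 tags 0.009, against 0.0104 to 0.0143 in the other lists). These p-values rest on the genome size in the headers, the human setting, and were not recomputed with a mouse size. The difference shrank only at much stricter cut-offs. Number 3 had 41177 peaks against 12441 in number 4 at p of 1e-03, and 17657 against 7690 at p of 1e-04. At p of 1e-05 the isotype list of number 3 was 1.15 times (1.1 to 1.2) as long. Its 11069 peaks of 3 tags are not the whole difference, since without them the list was still 3.06 times (3.01 to 3.12) as long, with 24090 peaks of 4 tags against 1981 to 2515 in the others. Whether the cut-off also let in those peaks of 4 tags was not tested, so other causes of many weak peaks stay open.

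Every pair of lists overlapped beyond chance, whichever the antibody. After removal of unplaced sequence, chromosome Y and 10 kb around regions held by all lists, the overlap was at least 8.26 times chance in each of the 6 pairs. This argues against the removed sequence as the whole cause. Repeats called in fewer lists were not removed, so they stay open. Uneven peak density as the whole cause is argued against by at least 6.42 times when peaks were moved by 10 to 100 kb. The single input used for all 4 lists stays open and was not tested, as does chromatin that any antibody may recover.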
